A study of Mus musculus with 41 samples.

How the data were processed

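RNA was extracted with TRIzol from the cortex, midbrain or cerebellum of each animal and polyadenylated RNA was made into libraries with an NEBNext Ultra kit, which does not mark strand, per the labels' protocols. Paired reads were sequenced on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name STAR, Salmon, DESeq2 and the mouse build mm10, with no version or order of steps. The deposited table is called raw counts, but its values are a signal that had been normalised before the authors deposited it. Library totals were nearly equal, while the value of 1 read, read from the spacing of the low values, differed up to 10.8-fold between libraries. Of 75778 low values (up to 4.5 steps), 86.8% lay within 0.1 of a whole multiple of that step, so whole reads were not recovered for the rest and no count model was used. The spacing gave an estimate of the reads behind each library. The normalisation step itself is not given in the sources used here. It removes differences of depth between library totals, but a shallow library still has a larger error, most of all for low genes.

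The table had 24972 entries. The 26 entries whose gene name had become a date were left out (at most 0.351% of a library total), and 24946 were kept, of which 3197 were 0 in every library. No pair of libraries was identical (highest correlation 0.99). Libraries were grouped by the genotype and tissue in their labels, and replicate numbers came from the titles. A floxed and a cKO library whose title code and tissue label name different regions were left out of the comparisons. Libraries whose Xist and Y-linked values go against their sex label stayed in their groups.

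Each region was fitted alone in R 4.3.3 with limma 3.58.1, with trend and robust variance estimates, on log2(value + 1) with labelled sex as a covariate. Genes with a value of 10 or more in at least as many libraries as the smaller group were tested. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold minimum. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The design fixed at the start assumed counts and a count-based quasi-likelihood test. As the values were not counts, limma took its place with the same groups and covariate. Differences of the genotype effect between regions were contrasts of a fit of all 6 groups, and the labelled-sex interaction was a contrast of a fit of genotype by labelled sex. Each library comes from a separate animal within a region, and the regions come from the same animals.

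Gene lists were tested with camera at a preset correlation of 0.01 between genes, again with a correlation estimated for each list, and with fry, which asks whether a list moves one way without setting it against other genes. Of 43 lists, 42 had tested members, and the mitochondrially encoded genes were absent from the table. Counts of called members were made over all genes tested and adjusted over the list alone. The groups, covariates, lists, rule for named genes and first set of alternatives were chosen before the data were examined. The rule names Yy1, Gfap, Aldh1l1, Slc1a2, Slc1a3, Glul, Aqp4 and S100b in every region, and the 7 largest rises and 7 largest falls per region among called genes of mean log2 CPM of 0 or more with the same sign in both labelled sexes. It adds up to 3 members of each list with the lowest p, up to 8 genes called the same way in all regions, up to 4 per interaction, and the sex-linked genes. Symbols that are only identifiers were left out.

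Depth was compared between genotypes with two-sided exact permutation tests. Overlap and correlation between regions were set beside 100 permutations of genotype over whole animals, and overlap also beside that of independent lists. Each comparison of groups of at least 3 libraries was repeated on 100 splits of its libraries, the real one included. Alternatives changed the pseudocount, filter, scaling, covariates, library weights, block and libraries, 1 choice at a time. Coordinates are from GENCODE vM21 on GRCm38, the build mm10 names, and 97.9% of gene names (24420) matched 1 gene of it. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

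The tests were tested on simulated data with known changes. At a fold of 2, 85.1% of changed genes were recovered in cortex, 94.0% in midbrain and 77.3% in cerebellum, and at a fold of 1.5 the shares were 65.7%, 80.0% and 51.5%. Unchanged genes made up 5.1%, 6.7% and 5.7% of the calls. For differences between regions they made up 7.4% (midbrain against cortex), 19.8% (cerebellum against cortex) and 13.8% (cerebellum against midbrain), so those counts may hold more false calls than the threshold states. The simulation drew each library and each gene independently, though the regions share animals and genes of many lists were correlated. It changed fewer genes than were called within each region and in the contrasts with cerebellum. Its shares need not carry over to the real counts. With library weights by region the 3 shares were 12.8%, 12.5% and 10.9% in the same order.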

Results

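Polyadenylated RNA was sequenced from the cortex, midbrain and cerebellum of C57BL/6J mice aged 12 weeks. Floxed mice carry Yy1 alleles that Cre recombinase can excise. Conditional knockout mice (cKO) carry in addition Cre under the promoter of Gfap, which encodes an intermediate filament protein of astrocytes, and the labels call the knockout astrocyte-specific. Yy1 encodes a zinc finger transcription factor that can activate or repress its target genes. The title of the series names apoptosis, oxidative stress, inflammation and brain development, and the comparison of cKO with floxed tissue in each region addresses these. No group carried Cre without floxed Yy1 alleles, so loss of Yy1 and an effect of Cre itself cannot be told apart. The table held 41 libraries, each from the tissue of 1 animal. The comparisons used 39 of them, with 6 floxed and 5 cKO libraries of cortex, 7 floxed and 7 cKO libraries of midbrain, and 7 floxed and 7 cKO libraries of cerebellum. The other 2 libraries, 1 floxed and 1 cKO, have a title code of the cortex series and a tissue label of midbrain, and they were kept out of the comparisons. Values were normalised read counts, so library totals spanned only 21.6 to 28.9 M. The reads behind each library, estimated from the spacing of its low values, ranged from 6.83 to 69.7 M. Median estimated reads were 29.2 M in floxed and 28.5 M in cKO cortex, 29.3 and 22.8 M in midbrain, and 28.9 and 16.3 M in cerebellum. The mean difference in log2 reads, cKO minus floxed, was -0.35 in cortex (two-sided exact permutation p = 0.398), -0.41 in midbrain (exact permutation p = 0.0530) and -0.76 in cerebellum (exact permutation p = 0.0594).

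Yy1 (GRCm38 chromosome 12, 108792973 to 108820148, plus strand) was lower in cKO tissue of each region. In cortex its level was 1286 ± 119.7 normalised reads in floxed mice (SD, n = 6) and 1065 ± 99.2 in cKO mice (SD, n = 5), and the log2 fold was -0.26 (SE 0.07, limma adjusted p = 0.0166). In midbrain it was 1147 ± 132.6 and 969.3 ± 53.3 (SD, n = 7 and 7), a log2 fold of -0.24 (SE 0.06, limma adjusted p = 0.0180). In cerebellum it was 1059 ± 255.5 and 566.8 ± 63.6 (SD, n = 7 and 7), a log2 fold of -0.86 (SE 0.15, limma adjusted p = 0.00114). Every cKO library lay below the floxed mean of its region. The genotype effect on Yy1 was lower in cerebellum than in cortex by -0.60 (SE 0.16, limma adjusted p = 0.00863) and than in midbrain by -0.63 (SE 0.15, adjusted p = 0.00243). The values cover the whole gene, the deleted part is not given in the labels, and the tissue holds many cell types besides astrocytes. The library labelled floxed cerebellum 6 had 585.4 normalised reads of Yy1, inside the range of the cKO cerebellum libraries (498.8 to 682.6) and below the other floxed libraries (881.2 to 1348.3). In cortex the call was lost with the Xist level in place of labelled sex (log2 fold -0.22) and when all 6 groups shared 1 fit (-0.26). In midbrain it was lost with sequencing depth as a covariate (-0.24), without the libraries numbered 5, 6 and 7 (-0.27), and in the shared fit (-0.24).

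**Figure D1:**
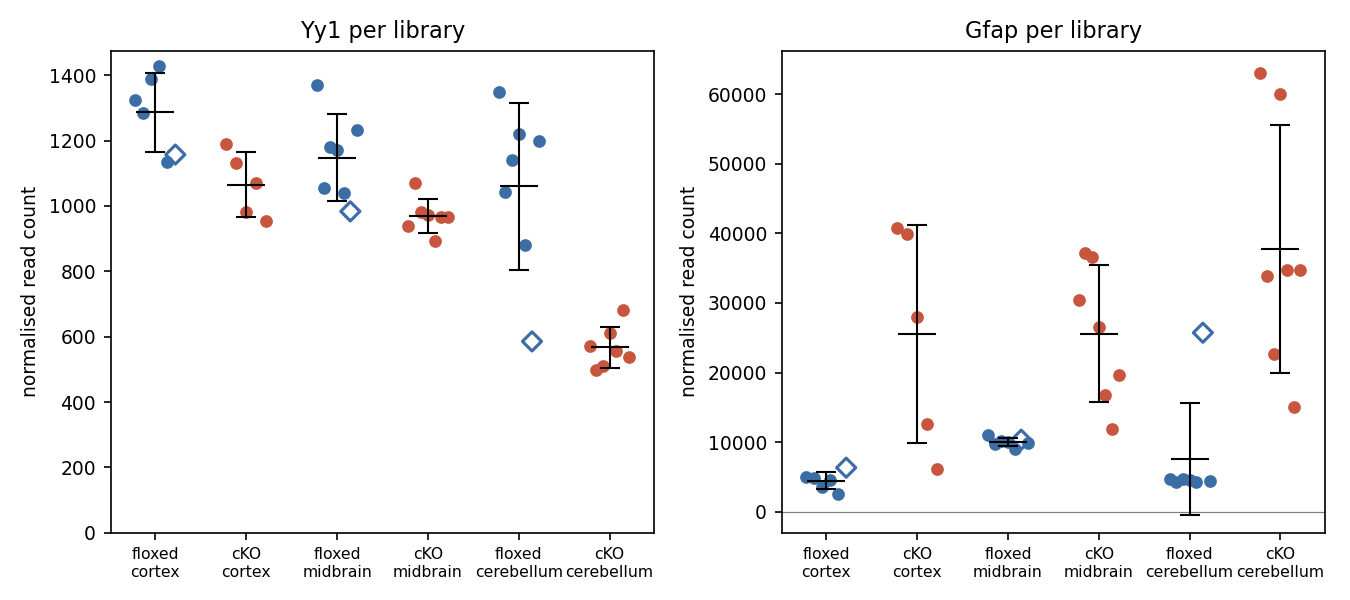
Normalised read counts of Yy1 (left) and Gfap (right) in each library of the 6 groups, with floxed libraries in blue and cKO libraries in red. Horizontal marks are group means and bars are SDs. Open diamonds are the libraries of floxed animal 6, which in cerebellum had 585.4 reads of Yy1 and 25729.2 of Gfap.

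Sex labels were checked with Xist, the transcript that silences one X chromosome in females, and with Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y. All 23 libraries labelled male carried the Y-linked transcripts. Of 18 libraries labelled female, 9 had 8232.2 to 17250.6 normalised reads of Xist and at most 7.4 of Ddx3y. The other 9 had 3.5 to 22.1 reads of Xist and 543.2 to 1096.8 of Ddx3y. These 9 were all libraries of the animals labelled floxed 5, floxed 6 and cKO 7, and 8 of them were in the comparisons. Libraries stayed in the groups their labels give, and labelled sex was a covariate of each genotype comparison.

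**Figure D2:**
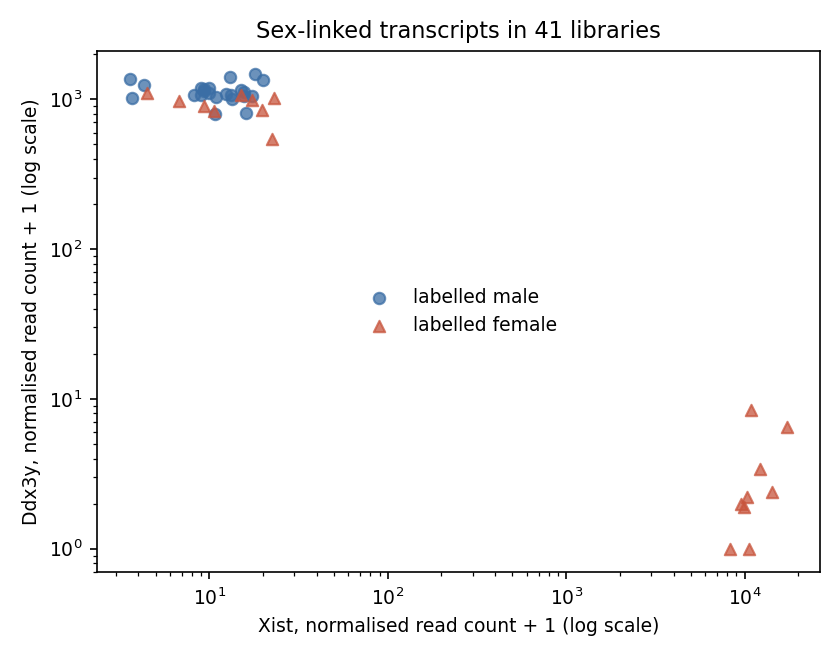
Normalised read counts plus 1 of Xist (horizontal, log scale) and Y-linked Ddx3y (vertical, log scale) in the 41 libraries, with libraries labelled male as blue circles and libraries labelled female as red triangles. Of the libraries labelled female, 9 lie with those labelled male.

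In cKO cortex Gfap rose, and the astrocyte genes Aqp4, Slc1a2 and Glul fell. Gfap (chromosome 11, 102887336 to 102900912, minus strand) rose from 4499 ± 1261 normalised reads in floxed (SD, n = 6) to 25520 ± 15690 in cKO cortex (SD, n = 5), a log2 fold of 2.31 (SE 0.40, limma adjusted p = 0.00519). Aqp4 (chromosome 18, 15389496 to 15410982, minus strand), the water channel of astrocyte endfeet, fell by 1.11 on the log2 scale (SE 0.21, adjusted p = 0.00509). Slc1a2 (chromosome 2, 102658659 to 102790784, plus strand), the main glutamate transporter, fell by 0.90 (SE 0.14, adjusted p = 0.00141), from 63150 ± 18810 to 32360 ± 4030 reads. The glutamine synthetase gene Glul fell by 0.55 (SE 0.13, adjusted p = 0.0115). The glutamate transporter gene Slc1a3 had a log2 fold of -0.21 (SE 0.11, adjusted p = 0.166), S100b, for a calcium-binding protein, one of -0.77 (SE 0.27, adjusted p = 0.0661), and the folate enzyme gene Aldh1l1 one of 0.03 (SE 0.14, adjusted p = 0.899). S100b passed the threshold without the library labelled floxed cortex 6 (adjusted p = 0.00287) or cKO cortex 6 (0.0274), and Slc1a3 without floxed cortex 5 (0.0337). Aldh1l1 had a negative fold with depth as a covariate (-0.04) and without floxed cortex 3 (-0.03), floxed cortex 4 (-0.05) or cKO cortex 2 (-0.05).

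The largest rises in cortex were in Cxcl10 (chromosome 5, 92346638 to 92348889, minus strand), a chemokine gene, with a log2 fold of 4.60 (SE 0.50, adjusted p = 0.000338), and in Serpinf2, which encodes the plasmin inhibitor, with 4.10 (SE 0.55, adjusted p = 0.000836). Oas1g (3.86, SE 0.44), Oasl2 (3.85, SE 0.48) and Oas1a (3.75, SE 0.38) of the oligoadenylate synthetase family rose with Zbp1, a nucleic acid sensor (3.85, SE 0.70). The Oas genes resemble each other in sequence, so the share of reads of each is uncertain. S100a5, for a calcium-binding protein, had a log2 fold of 4.20 (SE 1.36, adjusted p = 0.0482), but leaving out 1 library ended its call in 9 of 10 fits (adjusted p up to 0.124). The largest falls were in Egfl6, a secreted protein with EGF repeats (-3.12, SE 0.42), Etnppl, a phosphoethanolamine lyase (-3.06, SE 0.53), the matrix protein gene Thbs4 (-2.63, SE 0.39), the polarity cadherin gene Celsr1 (-2.42, SE 0.27), Ppp1r3g, a glycogen-targeting phosphatase subunit (-2.0, SE 0.41) and the ferroxidase gene Heph (-1.90, SE 0.30). The insulin receptor substrate gene Irs4 (-2.16, SE 0.62, adjusted p = 0.0321) lost its call in 8 of 11 fits without 1 library (adjusted p up to 0.0902).

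Interferon-response genes rose together in cKO cortex, 28 of 29 by the test over all genes and 29 adjusted over the list alone, with a median log2 fold of 2.54 (camera adjusted p = 6.10e-27, and adjusted p = 0.267 with an estimated correlation). Examples were Isg15, a ubiquitin-like modifier (3.38, SE 0.32), Oas2 (3.45, SE 0.32) and Ifi27 (1.81, SE 0.15). The library floxed cortex 6 stood above the other floxed libraries at Ifi27 (1043.1 normalised reads, others 629.4 to 700.8) and Oasl2 (244.1, others 62.2 to 107.1). Of 23 complement and antigen presentation genes, 16 rose (17 adjusted over the list alone, median 1.34), with the immunoproteasome genes Psmb8 (2.18, SE 0.23) and Psmb9 (1.75, SE 0.21) and the class I light chain gene B2m (1.42, SE 0.17). Activated microglia genes rose in 14 of 18 cases (14 adjusted over the list alone, median 0.90), among them Gpnmb (2.20, SE 0.25), Lgals3 (2.36, SE 0.31) and the lysosomal gene Cd68 (1.21, SE 0.18). Of 25 cytokine and NF-kB genes 15 rose (18 rose and 1 fell adjusted over the list alone), and of 10 NADPH oxidase and nitric oxide synthase genes 6 rose (6 adjusted over the list alone), including the oxidase subunit genes Cyba (1.24, SE 0.15) and Rac2 (1.42, SE 0.19). Of 32 reactive astrocyte genes, a list that shares members such as Gbp2, Psmb8 and Cxcl10 with the immune lists, 21 rose and 1 fell (22 and 1 adjusted over the list alone). For each of these 6 lists the adjusted p was 0.267 with an estimated correlation.

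Microglial homeostatic markers also moved up in cortex, with 9 of 14 higher and 1 lower (9 and 1 adjusted over the list alone), for example Fcrls (1.07, SE 0.13) and Aif1 (1.28, SE 0.20), with camera adjusted p = 0.000185 and adjusted p = 0.436 with an estimated correlation. Of 23 cell cycle genes 11 rose (21 adjusted over the list alone, median 0.88), with the mitotic kinase gene Cdk1 at 2.14 (SE 0.30) and Cdc20, an activator of the anaphase complex, at 1.53 (SE 0.23). The adjusted p was 0.306 with an estimated correlation. Of 24 astrocyte markers 13 fell and 2 rose (14 and 3 adjusted over the list alone, median -0.47), with the GABA transporter gene Slc6a11 at -1.29 (SE 0.16) and the connexin gene Gja1 at -1.22 (SE 0.19). The adjusted p was 0.447 with an estimated correlation. Oligodendrocyte and myelin genes fell in 10 of 20 cases (14 adjusted over the list alone, median -0.55), including Tspan2 (-0.97, SE 0.16) and the myelin regulator Myrf (-0.62, SE 0.13). The adjusted p was 0.436 with an estimated correlation. Of 18 pro-apoptotic genes 5 rose (6 adjusted over the list alone), with the BCL2 family effectors Bax (0.42, SE 0.09) and Bak1 (0.48, SE 0.08), and of 22 p53 targets 8 rose (9 higher and 2 lower adjusted over the list alone), with the cell cycle inhibitor Cdkn1a (0.76, SE 0.15). Their adjusted p was 0.267 with an estimated correlation. Antioxidant genes rose in 8 of 31 cases and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0276), with the peroxiredoxin gene Prdx6 at 0.82 (SE 0.11), and the list was not called without cKO cortex 4 (adjusted p = 0.0636) or with an estimated correlation (adjusted p = 0.436 with an estimated correlation). Blood cell genes had a median log2 fold of -2.38, with 1 of 4 lower (4 adjusted over the list alone), and the adjusted p was 0.397 with an estimated correlation.

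Of the 52 genes named here and called in cortex, 51 had all 5 cKO libraries beyond the floxed mean and 43 had them beyond every floxed library. Chance gives the latter for 0.433% of genes taken at random, which is no test here because the genes were chosen as called. In all, 3693 of 15731 genes differed between cKO and floxed cortex by limma with labelled sex as a covariate and Benjamini-Hochberg adjustment, 1656 higher and 2037 lower. A fold of 2 or more was reached by 403 of the higher and 129 of the lower genes. Scaling to library totals alone turned this split to 2097 higher and 1444 lower. Of 42 lists, 15 were called up and 10 down by camera, none with an estimated correlation, and 24 by fry. All floxed cortex libraries carried Y-linked transcripts, while the cKO cortex libraries 5 and 6 carried Xist. Sex by these transcripts thus differed in part with genotype in cortex, and labelled sex did not adjust for this difference. Without the sex covariate 2040 genes were called, with Xist in its place 1623, and with all 6 groups in 1 fit 2302. In midbrain and cerebellum only floxed 7 and cKO 5 and 6 carried Xist. Sex by these transcripts was thus not balanced between genotypes there either, and labelled sex did not adjust for it.

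Gfap rose in cKO midbrain from 10060 ± 607.8 normalised reads in floxed to 25590 ± 9800 in cKO (SD, n = 7 and 7), a log2 fold of 1.25 (SE 0.16, limma adjusted p = 0.000356). Aqp4 (-0.94, SE 0.22), Slc1a2 (-0.43, SE 0.08), S100b (-0.51, SE 0.13) and Glul (-0.36, SE 0.09) fell, while Slc1a3 (-0.04, SE 0.06, adjusted p = 0.704) and Aldh1l1 (0.00, SE 0.09, adjusted p = 0.990) did not pass the test and changed sign under some settings. S100b was not called without the libraries numbered 5, 6 and 7 (adjusted p = 0.0661). The genotype effect on Gfap did not pass the test of a difference between midbrain and cortex (-1.02, SE 0.54, adjusted p = 0.998) or between cerebellum and midbrain (1.31, SE 0.50, adjusted p = 0.0569). Serpinf2 had the largest rise (4.34, SE 0.43, adjusted p = 4.58e-05), followed by Cxcl10 (3.92, SE 0.44), the helicase gene Ddx60 (2.96, SE 0.37), Mx1, an antiviral GTPase gene (2.91, SE 0.39), and Oas1a (2.86, SE 0.30). Ifi209 (2.91, SE 0.46) and Ifi204 (2.86, SE 0.42) belong to 1 gene family of similar sequence and are uncertain. The largest falls were in Thbs4 (-2.81, SE 0.44), Celsr1 (-1.91, SE 0.27), Bbox1, of carnitine synthesis (-1.88, SE 0.27), the D-amino acid oxidase gene Dao (-1.84, SE 0.24), Ppp1r3g (-1.70, SE 0.30), the erythroid haem synthesis gene Alas2 (-1.65, SE 0.36) and Papss2, of sulfate activation (-1.64, SE 0.24).

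Of 29 interferon-response genes 28 rose in midbrain (28 adjusted over the list alone), with a median log2 fold of 1.81 (camera adjusted p = 3.71e-33, and adjusted p = 0.194 with an estimated correlation) and examples in Usp18, which removes ISG15 from proteins (2.62, SE 0.21), and the GTPase gene Gbp3 (2.75, SE 0.26). The library floxed midbrain 6 stood above the other floxed libraries at Gbp3 (290.2 normalised reads, others 90.2 to 150), Ddx60, Serpinf2, Mcm3 and Aen. Of 23 complement and antigen presentation genes 15 rose (16 adjusted over the list alone, median 0.82), with C4b (1.14, SE 0.13) and Nlrc5, a regulator of class I genes (1.69, SE 0.20). For both lists, and for cytokine and NF-kB genes with 10 higher and 2 lower of 25 (12 and 3 adjusted over the list alone), among them the chemokine gene Ccl12 (2.83, SE 0.35), the adjusted p was 0.194 with an estimated correlation. Activated microglia genes rose in 12 of 19 cases (13 rose and 1 fell adjusted over the list alone), with Cst7, a protease inhibitor gene (2.78, SE 0.31), and Gpnmb (1.49, SE 0.18). Cell cycle genes rose in 14 of 22 cases (20 adjusted over the list alone, median 0.54), with the replication helicase gene Mcm3 (0.84, SE 0.13). Of 10 NADPH oxidase and nitric oxide synthase genes 6 rose (6 adjusted over the list alone), and of 32 reactive astrocyte genes 13 rose and 2 fell (18 and 2 adjusted over the list alone). For these 4 lists the adjusted p was 0.223 with an estimated correlation. Homeostatic microglia markers were higher in 7 and lower in 1 of 14 cases (7 and 1 adjusted over the list alone), with adjusted p = 0.339 with an estimated correlation.

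Of 24 astrocyte markers 12 fell and 3 rose in midbrain (14 and 3 adjusted over the list alone, median -0.32), with Gja1 (-1.12, SE 0.18) and Cbs, of cysteine synthesis (-0.58, SE 0.10). The adjusted p was 0.405 with an estimated correlation. Oligodendrocyte and myelin genes fell in 12 of 20 cases (14 adjusted over the list alone, median -0.43), with Myrf (-0.55, SE 0.12) and the myelin glycoprotein gene Mag (-0.46, SE 0.10), and the adjusted p was 0.257 with an estimated correlation. Markers of vessels fell as well, with 10 of 18 endothelial markers lower (13 adjusted over the list alone), such as the VEGF receptor gene Flt1 (-0.72, SE 0.12), and 6 of 11 mural cell markers lower (8 adjusted over the list alone), such as the PDGF receptor gene Pdgfrb (-0.58, SE 0.08). Choroid plexus markers fell in 12 of 15 cases (15 adjusted over the list alone, median -0.83), and floxed midbrain 1 stood above the other floxed libraries at the markers Slc4a5 and Enpp2. For these 3 lists the adjusted p was 0.223 with an estimated correlation. Midbrain neuron markers fell in 9 of 20 cases (9 adjusted over the list alone), with the dopamine transporter gene Slc6a3 at -0.70 (SE 0.15), and the adjusted p was 0.237 with an estimated correlation. Striatal neuron markers rose in 10 of 12 cases (11 adjusted over the list alone, median 0.63), with the enkephalin gene Penk (0.69, SE 0.11) and the tachykinin gene Tac1 (0.51, SE 0.09), and the adjusted p was 0.223 with an estimated correlation. Of 18 pro-apoptotic genes 5 rose (7 adjusted over the list alone, adjusted p = 0.257 with an estimated correlation), and of 22 p53 targets 8 rose (10 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), with the p53-induced nuclease gene Aen (0.48, SE 0.06). Infiltrating and border immune cell markers rose in 3 of 7 cases (3 adjusted over the list alone, adjusted p = 0.194 with an estimated correlation), with the macrophage genes Mrc1 (1.24, SE 0.19) and Lyve1 (1.17, SE 0.20). Blood cell genes fell in 2 of 4 cases (3 adjusted over the list alone, median -1.44, adjusted p = 0.252 with an estimated correlation).

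Of the 51 genes named here and called in midbrain, 51 had all 7 cKO libraries beyond the floxed mean and 36 beyond every floxed library (0.0583% by chance for genes taken at random, which these were not). In midbrain 2524 of 15683 genes differed between cKO and floxed by limma, 1330 higher and 1194 lower, and 213 of the higher and 74 of the lower genes reached a fold of 2. Of 42 lists, 15 were called up and 10 down by camera, none with an estimated correlation, and 24 by fry. With sequencing depth as a covariate 721 genes were called, and with all 6 groups in 1 fit 961.

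The cerebellum had more genes called than the other regions, and Gfap rose from 7559 ± 8015 normalised reads in floxed to 37740 ± 17860 in cKO (SD, n = 7 and 7), a log2 fold of 2.55 (SE 0.42, limma adjusted p = 0.000884). The library labelled floxed cerebellum 6 had 25729.2 reads of Gfap, where the other floxed libraries had 4240.5 to 4785.6. Slc1a3 (-1.16, SE 0.20), Slc1a2 (-1.05, SE 0.20) and Aqp4 (-1.05, SE 0.19) fell, and Glul (-0.04, SE 0.08, adjusted p = 0.705) did not pass the test and had a positive fold of 0.03 when scaled to library totals. S100b (-0.64, SE 0.31, adjusted p = 0.109) passed without floxed cerebellum 6 (adjusted p = 0.0320), cKO cerebellum 4 (0.0374) or cKO cerebellum 7 (0.0290), and Aldh1l1 (0.30, SE 0.11, adjusted p = 0.0504) without floxed cerebellum 6 (0.0145) or cKO cerebellum 3 (0.0482), 4 (0.0467) or 6 (0.0143).

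The largest rises in cerebellum were in the secreted carbonic anhydrase gene Car6 (log2 fold 6.00, SE 1.11, adjusted p = 0.00145), the heparanase gene Hpse (5.69, SE 0.86), Serpina3n, a protease inhibitor gene of reactive astrocytes (5.26, SE 0.72), the transcription factor gene Tfap2c (4.74, SE 0.68), Cst7 (4.53, SE 0.80), the chemokine gene Ccl5 (4.38, SE 0.82) and the integrin gene Itgax (4.28, SE 0.67). All 7 stood far above the other floxed libraries in floxed cerebellum 6 as well, with Car6 at 435.0 normalised reads there. Npy (chromosome 6, 49822710 to 49829507, plus strand), which encodes neuropeptide Y, fell from 355.8 ± 123.9 to 18.7 ± 12.6 reads, a log2 fold of -4.30 (SE 0.37, adjusted p = 0.000144). Dao (-3.71, SE 0.56) and Lgr6, a receptor gene of WNT signalling (-3.53, SE 0.47), fell too. Prl2c3 (-4.05, SE 0.80) and Pcdha4 (-3.43, SE 1.06), which shares 49.7% of its exon bases with Pcdha1, have near copies and are uncertain, as are the pseudogene Oaz1-ps (-5.36, SE 1.82, adjusted p = 0.0325) and the chemokine gene Ccl21b (-3.62, SE 1.37, adjusted p = 0.0495). Leaving out 1 library ended the call of Oaz1-ps in 6 of 14 fits (adjusted p up to 0.0787) and of Ccl21b in 10 of 14 (adjusted p up to 0.0990).

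All 29 interferon-response genes rose in cKO cerebellum (29 adjusted over the list alone), with a median log2 fold of 2.17 (camera adjusted p = 4.32e-13, and adjusted p = 0.309 with an estimated correlation), including Oas2 (3.12, SE 0.46) and Ifitm3, a viral entry restriction gene (2.34, SE 0.38). Of 23 complement and antigen presentation genes 22 rose (23 adjusted over the list alone, median 2.16), with C4b (3.24, SE 0.47) and C1qa (2.63, SE 0.42). Of 19 activated microglia genes 17 rose (18 adjusted over the list alone, median 2.09), with the cathepsin gene Ctss (2.09, SE 0.34), and of 14 homeostatic microglia markers 13 rose (13 adjusted over the list alone, median 1.30), with the fractalkine receptor gene Cx3cr1 (1.78, SE 0.28) and the growth factor receptor gene Csf1r (1.44, SE 0.23). Cytokine and NF-kB genes rose in 25 of 30 cases (25 adjusted over the list alone, median 1.20) and reactive astrocyte genes in 24 of 33, with 2 lower (25 and 2 adjusted over the list alone). Meningeal fibroblast markers rose in 12 of 12 cases (12 adjusted over the list alone), with the matrix genes Dcn (2.12, SE 0.31) and Lum (2.12, SE 0.32). Of 23 cell cycle genes 15 rose and 1 fell (17 and 1 adjusted over the list alone), with the mitotic kinase gene Plk1 (1.47, SE 0.24). For these 8 lists the adjusted p was 0.309 with an estimated correlation. Infiltrating and border immune cell markers rose in 7 of 10 cases (7 adjusted over the list alone), with the leukocyte gene Ptprc (1.97, SE 0.39), and NADPH oxidase and nitric oxide synthase genes rose in 7 of 10, with 1 lower (7 and 1 adjusted over the list alone), with the oxidase subunit gene Ncf1 (2.34, SE 0.38). Their adjusted p was 0.325 with an estimated correlation. Floxed cerebellum 6 stood above the other floxed libraries at Ifitm3, C4b, C1qa, Ctss, Cx3cr1, Csf1r, Dcn, Lum, Ptprc and Ncf1. It had 2902.2 normalised reads of C4b (others 306.7 to 540.9) and 1614 of Dcn (others 306.5 to 571.6).

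Astrocyte markers fell in 16 of 24 cases in cerebellum (17 fell and 1 rose adjusted over the list alone, median -0.59), with the growth factor receptor gene Fgfr3 (-1.65, SE 0.17) and Gja1 (-1.80, SE 0.23). Bergmann glia markers fell in 6 of 8 (6 adjusted over the list alone, median -1.20), with Gdf10 (-3.24, SE 0.52) and Hopx (-1.23, SE 0.17). Purkinje cell markers fell in 10 of 12 (10 adjusted over the list alone, median -0.74), and synapse genes in 15 of 20 (16 adjusted over the list alone, median -0.51), with the glutamate receptor genes Grin2b (-1.29, SE 0.16) and Gria1 (-1.32, SE 0.20). For these 4 lists the adjusted p was 0.309 with an estimated correlation. Inhibitory neuron markers fell in 4 of 7 cases (5 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation), with the GABA synthesis gene Gad1 (-1.10, SE 0.22). The Purkinje cell list was called down in cortex too, with 6 of 11 lower (6 adjusted over the list alone). Its camera adjusted p there was 0.0240 (adjusted p = 0.267 with an estimated correlation). Cortical excitatory neuron markers were called down in cerebellum, with 6 of 13 lower (6 adjusted over the list alone, camera adjusted p = 0.0073). Their adjusted p was 0.309 with an estimated correlation. Such falls are thus not specific to the named cell type. Floxed cerebellum 6 stood below the other floxed libraries at Gja1, Gdf10, Hopx and Gria1, with 465 normalised reads of Gdf10 (others 5701.9 to 7721.9). As a list, oligodendrocyte and myelin genes were not called in cerebellum (camera adjusted p = 0.698), with 2 higher and 3 lower of 20 (2 and 3 adjusted over the list alone). Of 19 pro-apoptotic genes 9 rose and 2 fell (11 and 2 adjusted over the list alone), with Pmaip1, a BH3-only gene (2.09, SE 0.36), and of 23 p53 targets 12 rose and 3 fell (12 and 3 adjusted over the list alone), with Psrc1 (3.30, SE 0.49), and the adjusted p was 0.309 with an estimated correlation for both. Floxed cerebellum 6 stood above the other floxed libraries at Pmaip1 (109.8 normalised reads, others 15.1 to 27.6) and Psrc1 (80, others 4 to 9.9). Antioxidant genes were not called as a list (camera adjusted p = 0.149), with 10 higher and 3 lower of 31 (11 and 4 adjusted over the list alone), nor were they in midbrain (adjusted p = 0.225), with 7 higher and 3 lower (7 and 4 adjusted over the list alone). The list of 9 anti-apoptotic genes did not pass camera in any region (adjusted p = 0.615 in cortex, 0.880 in midbrain and 0.724 in cerebellum). Of its genes 2 were higher and 2 lower in cortex (2 and 2 adjusted over the list alone), 1 was higher in midbrain (2 higher and 2 lower adjusted over the list alone), and 2 were higher and 1 lower in cerebellum (2 and 1 adjusted over the list alone).

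Of the 59 genes named here and called in cerebellum, 57 had all 7 cKO libraries beyond the floxed mean and 18 beyond every floxed library (0.0583% by chance for genes taken at random, which these were not). In cerebellum 5980 of 15334 genes differed by limma, 2968 higher and 3012 lower, with 1116 and 426 at a fold of 2 or more. Without floxed cerebellum 6 there were 3158 higher and 3225 lower, 6383 in all. Scaling to library totals alone gave 3756 higher and 2175 lower. Of 42 lists, 13 were called up and 11 down by camera, none with an estimated correlation, and 24 by fry.

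**Figure D3:**
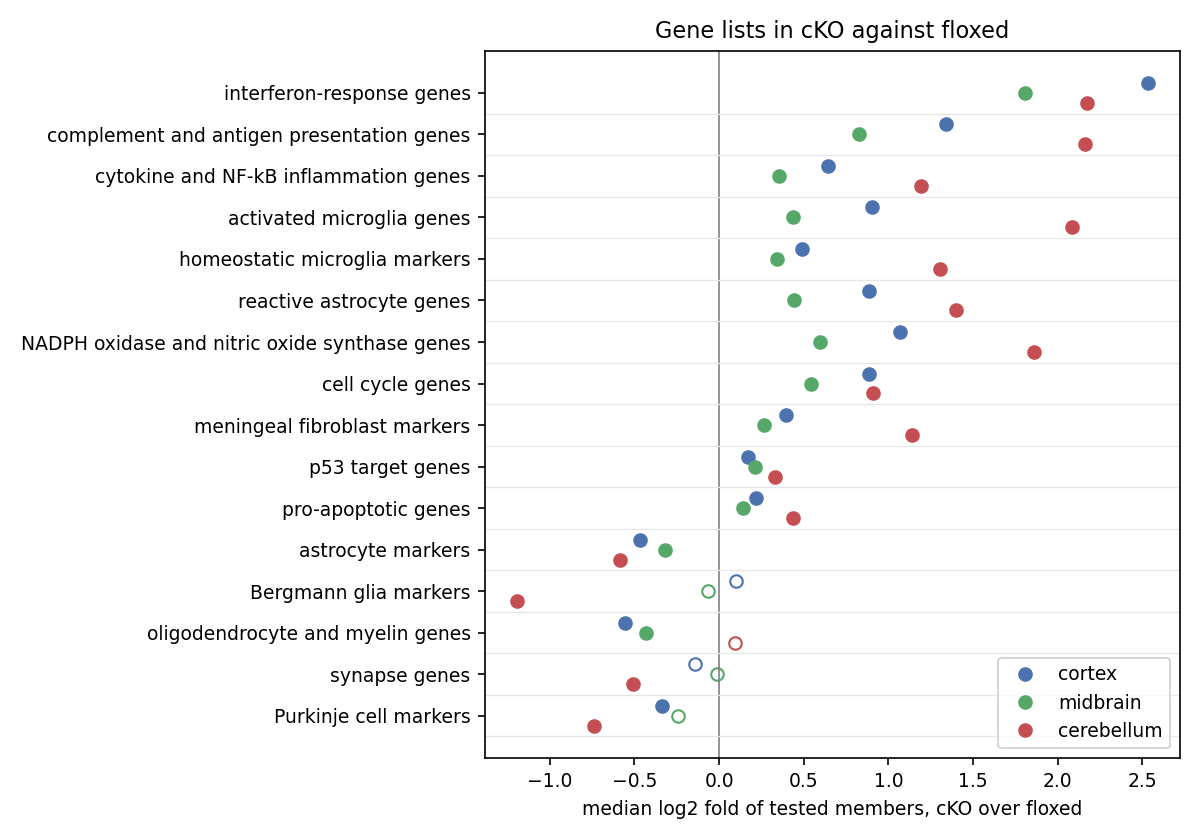
Median log2 fold, cKO over floxed, of the tested members of 16 gene lists (vertical) in cortex, midbrain and cerebellum. Filled points passed camera at adjusted p 0.05 with a preset correlation, open points did not. Interferon-response genes have medians of 2.54, 1.81 and 2.17.

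Genes called in the same direction in all regions numbered 1043, of 1079 called in all 3, with 677 higher and 366 lower in cKO. The endothelin receptor gene Ednrb (chromosome 14, 103814625 to 103844402, minus strand), which astrocytes express, fell by 1.38 on the log2 scale in cortex (SE 0.16), 1.08 in midbrain (SE 0.16) and 2.01 in cerebellum (SE 0.19). Timp4, an inhibitor of metalloproteinases, fell by 1.02 (SE 0.15), 0.74 (SE 0.09) and 1.04 (SE 0.16) in the same order. The adaptor gene Myd88 of Toll-like receptors rose by 0.87 (SE 0.12), 0.55 (SE 0.07) and 1.11 (SE 0.16), and Serpinf1, a secreted serpin gene, by 1.96 (SE 0.26), 1.11 (SE 0.14) and 1.32 (SE 0.19). Gsto2, a glutathione transferase gene, rose by 1.72 (SE 0.21), 1.25 (SE 0.18) and 1.86 (SE 0.28), and Oas2, Ifi27 and B2m completed the 8 genes of this kind with the lowest p. Libraries of floxed animal 6 stood apart from the other floxed libraries toward cKO at Serpinf1 in each region, at Gsto2 in midbrain and cerebellum, at Myd88 and Ifi27 in cortex and cerebellum, and at Timp4 and B2m in cerebellum. Cortex and midbrain shared 887 higher and 657 lower genes, where independent lists of those sizes would share 139.5 and 153.4, and 5 genes went opposite ways. Cortex and cerebellum shared 1054 and 1037 (305.3 and 393.2 if independent), with 89 opposite, and midbrain and cerebellum 845 and 510 (242.1 and 232.6), with 112 opposite. The value for independent lists leaves out that the regions come from the same animals. In 100 permutations of genotype over whole animals, no pair of regions shared a gene called the same way. The genotype effects stayed in the permuted values as added spread, which makes calls rarer, so this absence overstates the contrast.

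Over genes, which are not independent replicates, the log2 folds of cortex and midbrain had a correlation of 0.748 and a covariance of 0.108. The same permutations gave a median correlation of 0.374 (highest 0.722) and a median covariance of 0.0138 (highest 0.0875). For cortex and cerebellum the correlation was 0.632 (permuted median 0.264, highest 0.571) and the covariance 0.180 (permuted median 0.0162, highest 0.145). For midbrain and cerebellum it was 0.559 (permuted median 0.285, highest 0.556), with a covariance of 0.120 (permuted median 0.0114, highest 0.0844).

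**Figure D4:**
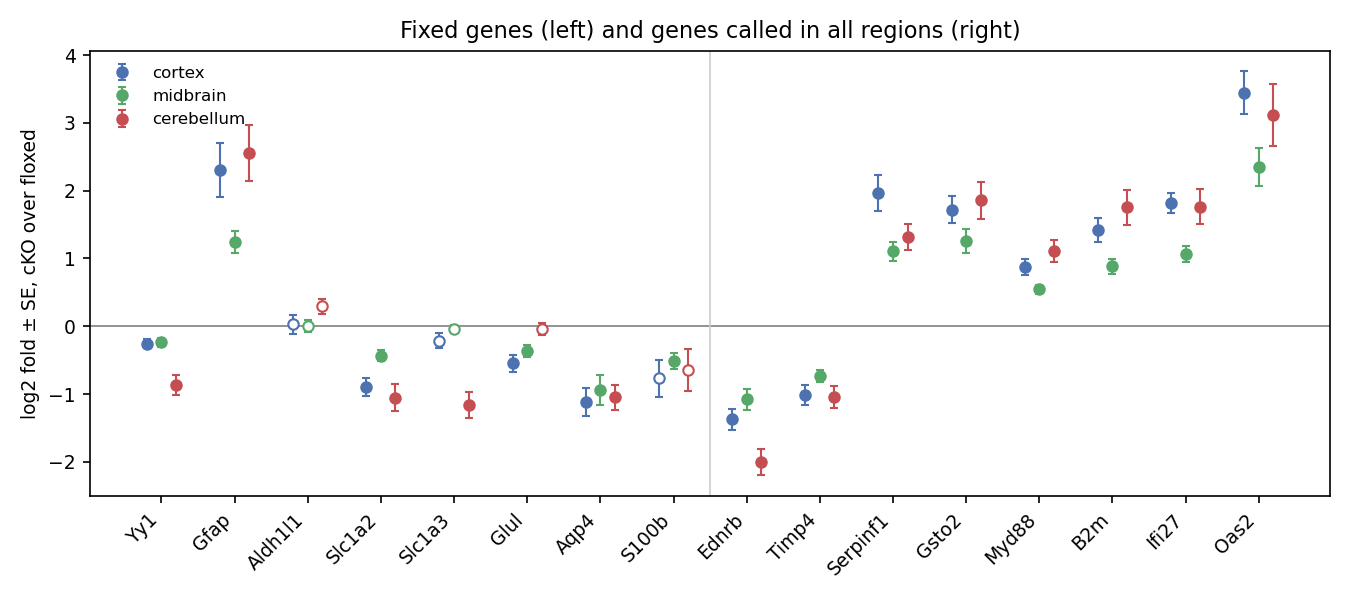
Log2 fold, cKO over floxed, with SE bars for the 8 genes fixed in advance (left of the line) and the 8 genes called in all regions with the lowest p (right). Filled points passed the adjusted p threshold of 0.05, open points did not. Gfap rises by 2.31, 1.25 and 2.55 in cortex, midbrain and cerebellum.

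Npy changed in opposite directions between regions. It rose in cortex (0.61, SE 0.15, adjusted p = 0.0124) and in midbrain (0.49, SE 0.14, adjusted p = 0.0223, but 0.0531 without floxed midbrain 1) and fell in cerebellum. Its genotype effect differed by -4.93 between cerebellum and cortex (SE 0.40, limma adjusted p = 2.64e-10) and by -4.79 between cerebellum and midbrain (SE 0.37, adjusted p = 8.64e-11). The effect on Gfra2, a receptor gene for neurturin, was lower in cerebellum than in cortex by -1.65 (SE 0.18), and that on the phosphatase gene Ptpdc1 was higher by 0.79 (SE 0.09). Cspg5, a proteoglycan gene (-1.62, SE 0.17), Jakmip1 (-1.26, SE 0.13) and the AMPA receptor auxiliary gene Shisa9 (-2.50, SE 0.27) had lower effects in cerebellum than in midbrain. Floxed cerebellum 6 stood apart from the other floxed libraries, toward cKO, at Gfra2, Ptpdc1, Cspg5 and Jakmip1. The effect on Slc1a3 was lower in cerebellum than in cortex by -0.94 (SE 0.22, adjusted p = 0.00285) and than in midbrain by -1.12 (SE 0.20, adjusted p = 0.000149). Ppm1j (chromosome 3, 104781056 to 104786018, plus strand), a protein phosphatase gene, rose in cortex (2.19, SE 0.25) and was not called in midbrain (-0.16, SE 0.20, adjusted p = 0.619, and 0.40 with the 2 conflicting libraries added), and the difference of -2.36 (SE 0.33, adjusted p = 0.000402) made it the 1 gene called between midbrain and cortex. Over 16659 genes, the genotype effect differed between cerebellum and cortex for 2414 genes (1066 higher, 1348 lower in cerebellum) and between cerebellum and midbrain for 3732 (1735 higher, 1997 lower). With each animal as a block, 3 genes differed between midbrain and cortex, and with library weights by region 10 did. Leaving out floxed 6 in all regions gave 6 for midbrain against cortex, and leaving out floxed 1 gave 1513 for cerebellum against cortex.

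The Y-linked genes and Xist led the differences tied to labelled sex in cortex. Within libraries labelled female the log2 fold of cKO over floxed was -7.58 for Uty, 9.11 for Xist, -6.12 for Eif2s3y and -7.17 for Kdm5d, and within libraries labelled male it was -0.46, -0.04, -0.13 and -0.41. The floxed cortex libraries labelled female, 5 and 6, carry Y-linked transcripts, and the cKO cortex libraries labelled female, 5 and 6, carry Xist, so these values follow from the labels. The genotype effect in libraries labelled female minus that in libraries labelled male was tested as an interaction. This interaction had 20 called genes in cortex, 5 without floxed cortex 1 and 126 without cKO cortex 4. It had 0 by limma in midbrain (1343 at unadjusted p under 0.05) and 0 in cerebellum (858 at unadjusted p under 0.05). Within libraries labelled male, genotype had 2746 called genes in cortex, 2937 in midbrain and 4608 in cerebellum. Within those labelled female it had 37, 15 and 0 by limma (2918, 1341 and 2982 at unadjusted p under 0.05). Fewer libraries are labelled female, and floxed 6 is among them, so these counts alone do not show that the effect differs. Libraries labelled female differed from those labelled male at 2252 genes in cortex (859 higher, 1393 lower), at 0 by limma in midbrain (1237 at unadjusted p under 0.05) and at 0 in cerebellum (962 at unadjusted p under 0.05). The cortex count was 20 without cKO cortex 6 and 4758 without cKO cortex 4. In midbrain and cerebellum the libraries of floxed 5, floxed 6 and cKO 7 are labelled female but carry Y-linked transcripts. The counts of 0 there concern the labels and do not decide whether the sexes differ.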

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

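The tests of explanations and the splits of libraries in this part were written down only after the result they concern was seen, except the pair that asks why libraries labelled female differed from those labelled male in cortex, while the gene list tests and the differences between regions and labelled sexes were planned.

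The library labelled floxed cerebellum 6 lay among the cKO libraries, with 25729.2 normalised reads of Gfap (others 4240.5 to 4785.6) and 6120.3 of S100b (others 12670.2 to 15398.9), a place apart from its group at 35 other named genes, and 69.74 M estimated reads (others 18.6 to 33.4). On an axis from 0 (floxed mean) to 1 (cKO mean) it scored 0.748, against -0.02 to 0.124 for the other floxed cerebellum libraries. An exchange of labels with a cKO cerebellum library is argued against, since the lowest score of a cKO library was 0.66 and none lay with the floxed libraries. A single wrong genotype label or an outside sample stays open, because the score of 0.748 only restates the pattern. That explanation also called for cortex and midbrain libraries of floxed 6 within the range of the other floxed libraries. Those libraries lay above it, at 0.37 in cortex (others up to 0.326) and 0.498 in midbrain (others up to 0.205). A wrong label of the whole animal stays open too, as its cortex and midbrain libraries lay between the genotypes (higher score 0.498), and so does a real response of a floxed animal, which was not tested.

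Libraries labelled female differed from those labelled male at 2252 genes in cortex and at none by limma in midbrain and cerebellum (1237 and 962 at unadjusted p under 0.05). In midbrain and cerebellum some libraries labelled female carry Xist and some carry Y-linked transcripts, so the absence of calls there decides nothing about sex. In cortex both floxed libraries labelled female carry Y-linked transcripts, and both cKO libraries labelled female carry Xist. The change from the lower numbers to 5 and 6 nevertheless had a correlation of 0.302 over 14975 genes between floxed and cKO, and 6 of 150 splits of the numbers, the real one included, gave one as large (highest other 0.375, median other 0.004). The floxed and cKO libraries labelled female differ in Xist, so a shared change would argue against the sex of the animals as the whole cause. The correlation of 0.302 does not decide this, because other splits gave values as large (up to 0.375). The count of 2252 genes also fell to 20 without cKO cortex 6. The sex of the animals thus stays open. A factor that goes with numbers 5 and 6 in both genotypes, such as a litter or a day, stays open too, and the labels name none.

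Interferon-response genes were higher in cKO in every region, with medians of 2.54, 1.81 and 2.17 in cortex, midbrain and cerebellum. Lower depth of the cKO libraries is argued against as the whole cause, because with depth as a covariate the medians were 2.467, 1.765 and 2.506 with 28, 27 and 28 of 29 genes called. Blood left in the tissue is argued against in cortex and midbrain by the medians of the blood cell genes (-2.379 and -1.435, fry adjusted p = 0.0258 and 0.0123) and stays open in cerebellum (-0.745, SD of the folds 0.894, fry adjusted p = 0.408). A lower share of astrocyte RNA would raise the genes of every other cell type alike, but the mean log2 change of interferon-response genes exceeded that of oligodendrocyte genes by 3.004, 2.237 and 2.046 (two-sided exact permutation p = 0.00217, 0.000583 and 0.00175). The oligodendrocyte genes themselves changed by -0.555, -0.44 and 0.106, so their fall is part of the difference in cortex and midbrain. The interferon-response genes alone changed by 2.449, 1.798 and 2.152. Infiltrating and border immune cells, whose markers were higher in 3 of 7 cases in midbrain, 7 of 10 in cerebellum and 1 of 8 in cortex (0 adjusted over the list alone by limma, 3 at unadjusted p under 0.05, median 0.26, camera adjusted p = 0.189, adjusted p = 0.436 with an estimated correlation), and the genotype itself stay open. The genotype joins loss of Yy1 with the presence of Cre, which the design does not separate.

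Other libraries stood apart from their group as follows, where chance alone gives about 1 in 20 groups. The library labelled floxed midbrain 5 had 48.59 M estimated reads (others 22.4 to 33.5), and floxed midbrain 1 had 59001.4 normalised reads of Slc1a2 (others 39357.6 to 46924.1). At other named genes, floxed midbrain 6 stood apart at 7, floxed cortex 6 at 5, cKO midbrain 4 at 3, and cKO cerebellum 4, floxed cortex 5, floxed midbrain 1 and cKO midbrain 2 at 2 each. The libraries cKO cerebellum 3, cKO cerebellum 7, cKO cortex 2, cKO cortex 4 and floxed cortex 3 did so at 1 each. In all a library stood apart in 63 of 294 groups of values of such genes (14.7 at 1 in 20), in 3 of 48 groups of values of the 8 fixed genes (2.4) and in 2 of 6 groups of depths (0.3).

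Genotype effects differed between labelled sexes at 20 genes in cortex, between midbrain and cortex at 1, between cerebellum and cortex at 2414 and between cerebellum and midbrain at 3732. The cKO library with conflicting region labels, which is in no comparison, lay above every floxed cortex and midbrain library at the interferon-response genes Oasl2 (1325 normalised reads, floxed 62.2 to 244.1), Ifi27 (2473.2, floxed 629.4 to 1046.8) and Isg15 (303.2, floxed 36.0 to 77.0). It did so also at Gfap (18225.2, floxed 2631.3 to 11059.5) and B2m (3988.7, floxed 1380.3 to 1714.3).

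Each comparison was set against 100 splits of its libraries, the real one included. Chance is excluded for the genotype counts, where 1 split was as large in cortex (3693, highest other 541), midbrain (2524, highest other 1249, in a split that put floxed 6 with most cKO libraries) and cerebellum (5980, highest other 4898). It is not excluded for the called lists, where other splits reached the real count in each region. These were cortex (25, 2 splits as large, highest other 25), midbrain (25, 7 splits as large, highest other 28) and cerebellum (24, 4 splits as large, highest other 25). The other splits called a median of 13 lists in cortex, 14 in midbrain and 16 in cerebellum, so list counts with the preset correlation were high in splits that ignore genotype as well. For labelled sex chance is excluded in cortex (2252, 1 split as large, highest other 18), but the count rests on 1 library, as it was 20 without cKO cortex 6. In midbrain and cerebellum labelled sex had 0 genes by limma (1237 and 962 at unadjusted p under 0.05), which all 100 splits reach by construction, so the splits decide nothing (highest other 2 and 0). The same holds for the labelled-sex interactions of midbrain and cerebellum with 0 genes by limma (1343 and 858 at unadjusted p under 0.05, highest other 21 and 2713, the latter a sign of structure among the cerebellum libraries). The cortex interaction has groups of 2 libraries and was not split. For the differences between regions chance is excluded for cerebellum against cortex (2414, 1 split as large, highest other 242) and cerebellum against midbrain (3732, 1 split as large, highest other 264). It is not excluded for midbrain against cortex (1 gene, 3 splits as large, highest other 1), where other splits reached the real count.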

How the results depend on the processing

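Settings with quality weights, depth or Xist covariates, other pseudocounts, weights by region, and those without floxed cerebellum 6 (for results between regions), without numbers 5 to 7 or without libraries that go against their sex label were chosen after the data were seen, all others before. Of values of named genes 97.1% (4720) kept direction and side of the threshold, 2.1% lost and 0.5% gained a call and 0.3% reversed, and of gene list calls 92.3% (1229) were kept and 7.7% lost. Of other results 326 were kept, 52 moved and 6 weakened. Estimated reads went down to 6.83 M in a cKO cerebellum library, and small changes of low genes are hard to see at such depth. A count-based Wald test and voom were not run, as the values are not counts. Except where fewer libraries or genes enter, the cause was not tested.

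Without a sex covariate cortex had 2040 called genes, with Xist as covariate in place of labelled sex 1623, and with all 6 groups in one fit 2302. Midbrain had 721 with log2 estimated reads as covariate and 961 with all groups in one fit. The Yy1 level in cortex lost its call with Xist (-0.218) and all groups in one fit (-0.261), and in midbrain with estimated reads (-0.243), without numbers 5, 6 and 7 (-0.266) and with all groups in one fit (-0.237). With an estimated correlation camera called 0 lists in cortex, 0 in midbrain and 0 in cerebellum, where fry called 24 in each. With no low-value filter the labelled-sex interaction had 6 genes in cortex and 1 in cerebellum, and labelled female against male in cortex 1482. Library weights by region gave 10 genes for midbrain minus cortex.

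Signs of uncalled genes reversed for Aldh1l1 in cortex with estimated reads (-0.036), Aldh1l1 in midbrain with the 2 conflicting libraries (-0.005), Slc1a3 in midbrain with quality weights (0.017), estimated reads (0.04) and the conflicting libraries (0.025), Ppm1j in midbrain without numbers 5, 6 and 7 (0.042) and with the conflicting libraries (0.404), and Glul in cerebellum with library totals only (0.03).

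The replicate numbers do not pair floxed with cKO libraries: same-numbered pairs had correlations over 0.1 in 2 of 5 cases in cortex, 0 of 7 in midbrain and 2 of 7 in cerebellum. With the replicate block cortex had 1164 called genes (midbrain 1941, cerebellum 4333), Yy1 in cortex was not called (-0.262), and the labelled-sex interaction in cortex had 6 genes. Shared calls under the block were 439 higher and 256 lower for cortex and midbrain, 485 and 272 for cortex and cerebellum, 329 lower for midbrain and cerebellum, and 369 higher and 146 lower in all regions. With a block of each animal, which the regions share, midbrain minus cortex had 3 genes.

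Leaving out 1 library at a time gave 2513 to 3607 genes in cortex, 1939 to 2932 in midbrain and 4690 to 6490 in cerebellum. It gave -0.054 to 0.113 for Aldh1l1 in cortex, -0.049 to 0.041 for Aldh1l1 in midbrain and -0.077 to 0.007 for Slc1a3 in midbrain. The labelled-sex interaction ranged from 5 to 126 genes in cortex, 0 to 1 in midbrain and 0 to 1 in cerebellum, and labelled female against male from 20 to 4758 in cortex and 0 to 3 in midbrain. Without 1 animal or floxed cerebellum 6, midbrain minus cortex ranged from 1 to 6 genes and cerebellum minus cortex from 1513 to 3339.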

Other observations

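Lists outside the themes of the series title also moved in cerebellum. Hedgehog pathway genes fell in 5 of 8 cases (5 adjusted over the list alone, median -1.05, camera adjusted p = 0.0313, adjusted p = 0.309 with an estimated correlation), with the receptor gene Ptch1 (-1.12, SE 0.22). In cortex 3 of 8 fell (3 adjusted over the list alone, median -0.35, adjusted p = 0.415 with an estimated correlation), with Hhip, a hedgehog-binding protein gene (-0.99, SE 0.18). Immediate early genes fell in 6 of 14 cases in cerebellum (6 adjusted over the list alone, median -0.56, camera adjusted p = 0.0216, adjusted p = 0.309 with an estimated correlation), with the transcription factor genes Fos (-1.96, SE 0.34), Egr1 (-0.90, SE 0.17) and Egr4 (-1.54, SE 0.25). Cholesterol synthesis genes fell in 7 of 18 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.00920, adjusted p = 0.494 with an estimated correlation). The regulator gene Srebf2 (-0.66, SE 0.15) fell, and the reductase gene Dhcr7 (0.32, SE 0.08) rose. Th (chromosome 7, 142892752 to 142931128, minus strand), which encodes tyrosine hydroxylase, rose by 2.63 (SE 0.51), and the library labelled floxed cerebellum 6 had 3837 normalised reads of it where the other floxed libraries had 267.5 to 545.3.

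Choroid plexus markers fell in 6 of 10 cases in cortex and rose in 1 (8 and 1 adjusted over the list alone, median -0.83, adjusted p = 0.306 with an estimated correlation), with Enpp2, for a secreted lysophospholipase, at -0.61 (SE 0.11) in cortex and -0.86 (SE 0.17) in midbrain. They were not called in cerebellum (camera adjusted p = 0.749), where 0 of 15 were called by limma. In midbrain the bicarbonate transporter gene Slc4a5 fell by 1.34 (SE 0.26). At both genes the library labelled floxed midbrain 1 stood apart from its group, with 239.2 normalised reads of Slc4a5 (other floxed libraries 78.2 to 124.5) and 20065 of Enpp2 (others 8107.4 to 10823), and without it the log2 fold was -1.17 for Slc4a5 in midbrain and -0.71 for Enpp2 in midbrain, both called by limma. Unfolded protein and integrated stress response genes rose in 6 of 21 cases in cortex and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00958, adjusted p = 0.436 with an estimated correlation), with the transcription factor gene Atf5 at 0.92 (SE 0.09), and the list was not called by camera in midbrain (adjusted p = 0.438), with 2 higher and 2 lower (3 and 2 adjusted over the list alone), or cerebellum (adjusted p = 0.724), with 3 higher and 2 lower (3 and 2 adjusted over the list alone). As a list, genes of complexes that partner with YY1 did not pass camera in cortex, midbrain or cerebellum (adjusted p = 0.550, 0.473 and 0.724). Of its 18 genes limma called 1 higher in cortex (0 adjusted over the list alone, 6 at unadjusted p under 0.05), 0 in midbrain (0 adjusted over the list alone, 1 at unadjusted p under 0.05), and 4 higher and 3 lower in cerebellum (4 and 3 adjusted over the list alone). The list of circadian clock genes did not pass camera either (adjusted p = 0.0689, 0.812 and 0.458), though fry called it down in cortex (adjusted p = 0.0319). Of its 13 genes 4 were lower in cortex, 1 was higher in midbrain and 5 were lower in cerebellum (4, 1 and 5 adjusted over the list alone).

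The 2 libraries with conflicting region labels, 1 floxed and 1 cKO, lay below every midbrain library at 3 genes of midbrain neurons. Gata3 was listed at 0 in both (midbrain 88.9 to 196.5), En1 had 1.4 and 1.2 normalised reads (midbrain 51.0 to 213), and the dopamine transporter gene Slc6a3 had 2.7 and 42.2 (cortex 3.3 to 22.9, midbrain 209.4 to 767.6). The same libraries had 1191.3 (floxed) and 1062.8 (cKO) reads of Yy1, 1676 and 1020.6 of Aqp4, and 275.8 and 62.8 of Celsr1.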
